A study of Mus musculus with 28 samples.

How the data were processed

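Gene expression was measured by bulk RNA-seq of total RNA in 28 libraries from kidneys of male mice. Per the labels, RNA was extracted with TRIzol and an RNeasy kit and libraries were prepared with a Nextera XT kit. The groups were db/m intact mice at 26 weeks (n = 5) and 35 weeks (n = 6), and db/db mice with 1 kidney removed (uninephrectomized, Unx) at 26 weeks (n = 12) and 35 weeks (n = 5). Each library was taken as 1 animal, which the labels do not state. If some libraries share an animal, p-values measure only the spread between libraries, which may be technical. Every db/db animal was uninephrectomized and every db/m animal was intact, so that genotype and surgery form 1 contrast, called the disease comparison here. The labels give no sequencing or library batch, so a batch that differed between the ages cannot be told apart from age.

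The deposited table holds 1 signal value per gene and library, for 14845 Ensembl gene identifiers and 28 libraries, with 0 value columns that belong to no sample. Per the submitters' processing notes, reads were processed with DRAGEN against the mouse genome build GRCm38 (mm10). The version of DRAGEN, the gene annotation, the scaling method and the rule by which genes entered the table are not given in the sources used here. The values were checked for their step size. In each library, 88.4% to 91.6% of the low values lay within 0.1 of a whole multiple of 1 library-specific step. Of the deposited values under 20, 100% lay on multiples of a hundredth of that step, within 0.01 of such a hundredth. The deposited signal values were therefore treated as estimated read counts multiplied by 1 scaling factor per library. Dividing by the step gave 21.8 to 30.8 M (M, mega) estimated counts per library. The column sums of the deposited values lay between 896873 and 1018930. The estimated counts were not whole numbers in enough cases for a count model, which was not run.

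Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which matched 14834 of the 14845 identifiers, and 11 stayed without a symbol. Genes with a value of at least 1 in at least 5 libraries, the size of the smallest group, were kept, which left 13495. The values were used as deposited, without a further normalization, as log2(value + 1). A linear model with 1 mean per group and a spread shared by the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes moderation. Contrasts were db/db Unx against db/m intact at 26 weeks, the same at 35 weeks, 35 against 26 weeks in db/db Unx, 35 against 26 weeks in db/m intact, and the difference between the disease comparisons of the 2 ages, called the interaction. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 13495 genes, and a gene was called at an adjusted p below 0.05 with no fold threshold. Adjusted p-values of single genes in the text are from limma. Fold changes are log2 differences with their moderated standard errors, and means are arithmetic means of the deposited values with SDs.

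Of gene and marker lists, 40 were fixed before the data were examined: 22 lists of gene functions (extracellular matrix and fibroblasts, injured tubule, chemokines with cytokines and NF-kB targets, complement, interferon response, MHC class II, fatty acid oxidation with PPARa targets, oxidative phosphorylation, mitochondrially encoded genes, glucose transport with gluconeogenesis and the polyol pathway, glycolysis, lipid and cholesterol synthesis and uptake, cell cycle, p53 targets and senescence, NRF2 targets, ER stress and integrated stress response, the renin-angiotensin system, male-biased and female-biased kidney genes, circadian clock, immediate early genes and heat shock) and 18 lists of cell type markers (proximal tubule, podocyte, thick ascending limb, distal convoluted and connecting tubule, principal cell, intercalated cell, endothelium, smooth muscle and mesangium, macrophage and monocyte, T and NK cell, B and plasma cell, neutrophil, erythroid, adipocyte, adrenal, urothelium, lymphatic and skeletal muscle). Each list was tested in each contrast with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and p-values were adjusted over the 40 lists. Camera with a correlation estimated per list and fry were run beside it. A list score is the mean over members of the log2 value minus that gene's mean over all libraries.

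The genes the text may name were also set by a rule written before the data were examined. Lepr comes first. In each disease comparison, the 8 genes per direction with the largest fold change were taken among called genes whose groups did not overlap and whose mean in the higher group reached the median of the tested genes' means (19.7), leaving out predicted genes and immunoglobulin or T cell receptor variable segments. For each list, up to 4 called members with the smallest adjusted p in either disease comparison were eligible, or up to 2 members with the highest mean where none was called. Of these members only some are printed, and which ones was decided after their values were seen. In each age comparison and the interaction, up to 5 genes per direction with the smallest adjusted p were taken. Not every gene that met the rule is printed. Genes outside this rule are said to have been chosen after their values were seen.

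The procedure was tested on simulated data in which 67, 67 and 66 of the 13495 genes were changed by 0.5, 1 and 2 on the log2 scale. At these changes, the share recovered was 64.2%, 89.6% and 100% in the 26-week disease comparison, 59.7%, 94.0% and 98.5% in the 35-week one, 68.7%, 97.0% and 95.5% for age in db/db, 58.2%, 89.6% and 98.5% for age in db/m, and 41.8%, 71.6% and 98.5% for the interaction. Of the calls in these simulations, 6.63%, 2.89%, 4.92%, 4.65% and 4.73% were false, in the same order. The simulated noise was normal and independent between genes and libraries, with 1 spread per gene in all 4 groups. These rates therefore do not cover groups of unequal spread, correlated genes or outlying libraries, and may not hold for the real data.

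Alternatives fixed before the data were examined were rescaling by the median of ratios or by TMM factors (trims of 30% and 5%), quantile normalization, no filter, a filter 5 times stricter, pseudocounts of 0.1 and 10, a fit of only the groups compared, no trend and no robust step, array weights, a fold threshold of 1 on the log2 scale, a block for the replicate number, leaving out each library, and an exact rank-sum test. Alternatives chosen after the data were seen were voom weights on the estimated counts, the removal of each library's trend on exon length or on transcript GC content, and list tests under TMM, quantile normalization and the removal of either trend and without each library in turn, and the count of shared calls without each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, exact tests and figures.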

Results

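The study addressed how the kidney transcriptome differs in a mouse model of severe diabetic kidney disease, the uninephrectomized db/db mouse, which lacks a functional long form of the leptin receptor and is obese and diabetic. Kidneys of male mice were profiled by RNA-seq in 28 libraries, each taken as 1 animal. The controls were intact db/m mice, 5 at 26 weeks and 6 at 35 weeks of age. The db/db Unx groups held 12 mice at 26 weeks and 5 at 35 weeks. Estimated depth averaged 24.6 ± 2.13 M counts (M, mega, SD, n = 5) in db/m at 26 weeks, 25.01 ± 3.29 M (n = 6) in db/m at 35 weeks, 24.8 ± 1.84 M (n = 12) in db/db Unx at 26 weeks and 27.5 ± 3.41 M (n = 5) in db/db Unx at 35 weeks. Single libraries ranged from 21.8 to 30.8 M. Libraries of 1 group correlated with Pearson r between 0.971 and 0.991 on log2 values across genes, which are not independent replicates. Means below are of the deposited, scaled values, given with the SD over the animals of a group in the numbers above, and fold changes are log2 values with their standard errors.

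The first principal component held 40.3% of the variance and separated all db/db Unx libraries from all db/m libraries. The second held 9.17%, and on it 3 of the 5 db/db Unx libraries of 35 weeks lay apart from all others, replicate 03 at -42.8, replicate 05 at -26.7 and replicate 06 at -20.1.

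**Figure D1:**
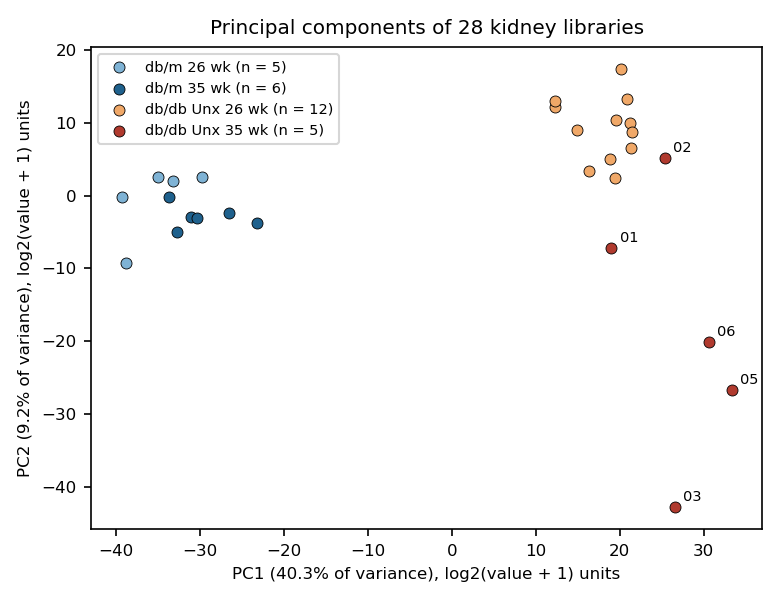
Scores of the 28 libraries on the first principal component (40.3% of variance) and the second (9.17%), computed on log2(value + 1). Each point is 1 library and the numbers beside points are replicates of the 35-week db/db Unx group, of which replicate 03 lies lowest on the second component at -42.8.

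The leptin receptor gene Lepr (ENSMUSG00000057722, GRCm38 chromosome 4, 101717404 to 101815352) is mutated in db/db mice. Its value summed over transcripts was low in every group, at 0.483 ± 0.205 in db/m and 0.745 ± 0.449 in db/db Unx at 26 weeks, and 2.17 ± 1.33 in db/m and 0.631 ± 0.447 in db/db Unx at 35 weeks. At 26 weeks the difference was not called (adjusted p 0.493). At 35 weeks the log2 change was -0.91 ± 0.24 (adjusted p 0.00309). A value per gene does not show the db mutation, which changes splicing, and so does not check the genotype labels.

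The comparison of db/db Unx with db/m at 26 weeks asked which transcripts differ in the diseased kidney. limma called 4713 of 13495 genes, 2318 higher and 2395 lower in db/db Unx. Of these, 542 changed by at least 2-fold, 268 up and 274 down. The values of 1725 genes did not overlap between the groups, 12.8% of the genes tested, where chance gives 0.0323%.

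Among the genes that rose at 26 weeks, Ugt1a2 (ENSMUSG00000090171, chromosome 1, 88200601 to 88218997) rose from 1.39 ± 1.24 to 269 ± 162, a log2 change of 6.75 ± 0.41 (adjusted p 1.18e-12). Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142) rose from 11.2 ± 5.10 to 824 ± 227, by 6.20 ± 0.29 (adjusted p 4.74e-15). Gc (ENSMUSG00000035540, chromosome 5, 89417522 to 89457898), which encodes the vitamin D binding protein, rose from 3.76 ± 1.56 to 144 ± 27.7, by 4.97 ± 0.16 (adjusted p 1.47e-19). Log2 changes of the other named genes were 5.59 for Gsta2, 4.82 for Bhmt, 4.62 for Ugt1a10 and 4.31 for Cyp27b1, with a highest adjusted p of 4.78e-13 for Bhmt. The Ugt1a genes share their last exons, and Gsta and Cyp4a genes have close paralogs, so the division of reads among members of these families is uncertain.

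Among the genes that fell at 26 weeks, Alox15 (ENSMUSG00000018924, chromosome 11, 70344152 to 70352031) went from 171 ± 35.8 to 2.38 ± 1.08, a log2 change of -5.71 ± 0.21 (adjusted p 1.07e-18). Slco1a1 (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962) went from 635 ± 122 to 24.9 ± 17.7, by -5.08 ± 0.54 (adjusted p 3.11e-08). The other named decreases were -4.78 for Slc22a7, -4.17 for Srd5a2, -4.10 for Acsm3, -3.77 for Slc7a13, -3.70 for Ccl28 and -3.54 for Angptl7, with a highest adjusted p of 1.08e-10 for Slc7a13. Slc22a7 has close paralogs, which leaves its reads uncertain.

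Camera called 14 of the 40 lists at 26 weeks, 11 higher and 3 lower. The male-biased kidney genes had the smallest adjusted p (1.89e-15) and a median log2 change of -2.18. Of the 13 members, 1 rose and 12 fell (1 and 12 adjusted over the list alone). Cyp4b1 fell from 8632 ± 1049 to 1991 ± 162, by -2.11 ± 0.07 (adjusted p 3.25e-21). Of the 5 female-biased genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 2.22 and an adjusted camera p of 0.000948 (0.0774 with an estimated correlation). Prlr rose by 2.29 ± 0.17 and Cyp2a4 changed by -1.34 ± 0.16. Cyp4a14 belongs to this list as well.

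Genes of tubule injury and matrix were also higher at 26 weeks. Of the 25 injured tubule genes, 20 rose and 1 fell (22 and 1 adjusted over the list alone), with an adjusted camera p of 3.29e-12 (0.0511 with an estimated correlation) and a median of 0.73. Spp1 rose from 758 ± 68.7 to 3632 ± 705, by 2.24 ± 0.14, and Lgals3, Cp and Clu rose by 0.96, 1.24 and 1.17. Among the 31 matrix and fibroblast genes, 12 rose and 1 fell (16 and 2 adjusted over the list alone), with an adjusted camera p of 0.0069 (0.463 with an estimated correlation). Col12a1 rose by 1.54 and Tgfbi changed by -0.83. For the 18 p53 and senescence genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone) (camera 0.000425, estimated correlation 0.148), and Cdkn1a rose from 4.12 ± 1.36 to 36.8 ± 7.67. For the 15 immediate early genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone) (camera 0.0246, estimated correlation 0.455).

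Metabolic lists called higher at 26 weeks were fatty acid oxidation with PPARa targets, glycolysis and glucose transport. Of 26 fatty acid oxidation and PPARa genes, 12 rose and 3 fell (12 and 4 adjusted over the list alone), with an adjusted camera p of 0.000367 (0.455 with an estimated correlation). Members went both ways, with Acaa2 at 1.41 and Acadm at -0.53. Of 15 glycolysis genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone) (camera 0.000367, estimated correlation 0.0774). Of 16 genes of glucose transport, gluconeogenesis and the polyol pathway, 9 rose and 1 fell (10 and 1 adjusted over the list alone) (camera 0.000948, estimated correlation 0.261), and Pck1 rose by 1.41 ± 0.21.

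Nephron segment markers moved apart at 26 weeks. Proximal tubule markers had a median of -0.22, and of 20 members 3 rose and 13 fell (3 and 14 adjusted over the list alone) (camera 0.00122, estimated correlation 0.191, but 0.485 after quantile normalization). Acsm2 fell the most, with a log2 change of -1.10 ± 0.07. Distal convoluted and connecting tubule markers were higher, with a median of 0.59, and of 10 members 8 rose and 0 fell (8 and 0 adjusted over the list alone) (camera 3.57e-06, estimated correlation 0.0774). Of 10 principal cell markers, 7 rose and 1 fell (8 and 1 adjusted over the list alone) (camera 0.00464, estimated correlation 0.261). Of 17 podocyte markers, 7 rose and 0 fell (7 and 0 adjusted over the list alone) (camera 0.00364, estimated correlation 0.213). Of the 6 B and plasma cell markers tested, 0 rose and 5 fell (0 and 5 adjusted over the list alone) (camera 0.0153, estimated correlation 0.0774). With the correlation estimated per list, the male-biased list held at 26 weeks (adjusted p 0.0455) and the other 13 did not, with the injured tubule list at 0.0511.

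At 35 weeks the disease comparison called 4357 genes, 2148 higher and 2209 lower. At least 2-fold changes numbered 666, of which 389 were up and 277 down. The values of 2447 genes (18.1%) did not overlap, where chance gives 0.433%. Between the ages, 3015 genes were called the same way, 1348 up and 1667 down, where independent lists would share 369 and 392. The ages share no libraries. Called genes changed in opposite directions in 12 cases, and log2 changes of the 13495 genes correlated with r = 0.80 across genes.

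Named genes with the largest increases at 35 weeks included 5 of those named at 26 weeks, with Ugt1a2 at 7.38 ± 0.47 and Cyp4a14 at 6.72 ± 0.32. The others were Gsta2, Gc, Ugt1a10, Ugt1a1 (4.54) and C3. C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), a complement gene, had 17.1 ± 2.30 in db/m and 421 ± 152 in db/db Unx, a log2 change of 4.47 ± 0.24 (adjusted p 8.08e-14). The largest decrease was in Slco1a1, from 480.4 ± 55.4 to 2.21 ± 2.12, by -7.43 ± 0.61 (adjusted p 4.12e-10), where db/db Unx replicate 01 had 5.75 and the others at most 2.50. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), the kidney androgen-regulated protein gene, went from 14649 ± 1492 to 788 ± 399.98, by -4.37 ± 0.31 (adjusted p 2.48e-11). Log2 changes were -6.18 for Alox15, -4.89 for Slc7a13, -4.55 for Acsm3, -4.35 for Akr1c14, -4.08 for Pzp and -4.07 for Slc22a7.

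**Figure D2:**
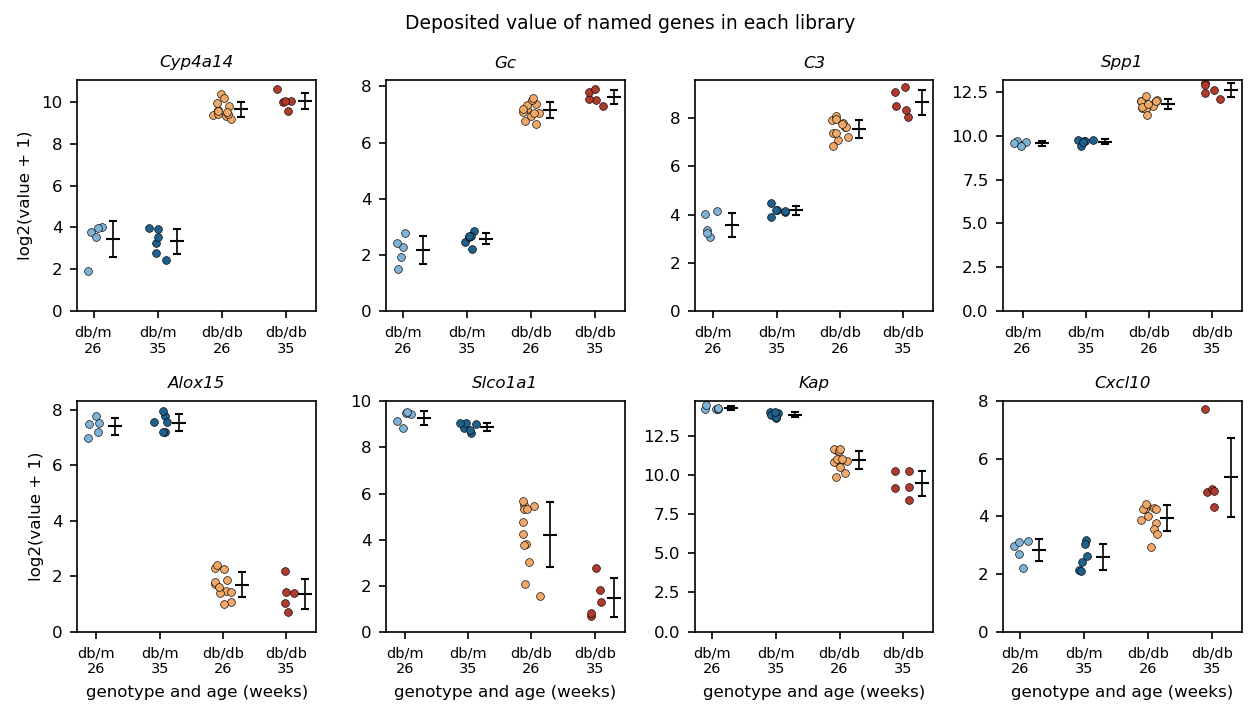
Deposited value as log2(value + 1) of 8 named genes in each library, by genotype and age in weeks. Points are libraries, and the dash and bar beside them are the mean and SD of the log2 values. Cyp4a14, Gc, C3 and Spp1 were higher and Alox15, Slco1a1 and Kap lower in all db/db Unx libraries than in all db/m libraries of the same age.

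Camera called 19 lists at 35 weeks, 16 higher and 3 lower. The injured tubule list came first (adjusted p 1e-21), with a median of 1.43, and of its 25 genes 24 rose and 1 fell (24 and 1 adjusted over the list alone). The male-biased list had a median of -2.81 (camera 6.02e-18), and of 13 genes 1 rose and 12 fell (1 and 12 adjusted over the list alone). These were the lists that held with an estimated correlation, at 0.00525 and 0.012. For the matrix list 20 rose and 0 fell (23 and 0 adjusted over the list alone) (camera 5.57e-08, estimated correlation 0.104). For the immediate early genes 13 rose and 0 fell (14 and 0 adjusted over the list alone) (camera 6.86e-07, estimated correlation 0.0738).

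Inflammatory lists were called at 35 weeks. Of 19 chemokine, cytokine and NF-kB genes, 13 rose and 1 fell (15 and 1 adjusted over the list alone), with an adjusted camera p of 1.65e-05 (0.18 with an estimated correlation). Cxcl10 had 5.24 ± 1.98 in db/m and 63.6 ± 83.3 in db/db Unx, a log2 change of 2.77 ± 0.41. For Cxcl10 replicate 03 had 212 and the other db/db Unx libraries at most 30.1, and without that replicate the log2 change was 2.17. Il34 changed by -1.27 ± 0.16. Of 13 complement genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone) (camera 0.00236, estimated correlation 0.18). Of 21 interferon response genes, 10 rose and 0 fell (14 and 0 adjusted over the list alone) (camera 6.65e-05, estimated correlation 0.405). The interferon score of db/db Unx replicate 03 was 2.58, against -0.30 to 0.67 in the other 4. Of 7 MHC class II genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone) (camera 0.000537, estimated correlation 0.315), and Cd74 had 338 ± 42.1 in db/m and 1639 ± 1176 in db/db Unx, by 1.84 ± 0.48 (adjusted p 0.00437). Of 21 macrophage and monocyte markers, 9 rose and 0 fell (9 and 0 adjusted over the list alone) (camera 0.000975, estimated correlation 0.405). The rise was not seen in db/db Unx replicate 02, with scores of -0.92 for MHC class II and -0.47 for macrophage markers, below all 35-week db/m libraries. At 26 weeks the adjusted camera p was 0.703 for the chemokine list, 0.413 for complement, 0.644 for interferon response, 0.419 for MHC class II and 0.213 for macrophage markers. Complement scores were nonetheless higher in every 26-week db/db Unx library (at least -0.108) than in every 26-week db/m library (at most -0.276). Scores of the other lists in this group overlapped at 26 weeks.

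Other lists called at 35 weeks were those of fatty acid oxidation with PPARa targets (16 rose and 4 fell (18 and 4 adjusted over the list alone), camera 3.04e-05, estimated correlation 0.315), the female-biased genes (0.000537, estimated correlation 0.0738), the p53 targets (0.000933, estimated correlation 0.18), glycolysis (0.000933, estimated correlation 0.114) and glucose transport (0.0107, estimated correlation 0.349), all higher. Proximal tubule markers were lower, and of 20 members 2 rose and 12 fell (2 and 12 adjusted over the list alone) (camera 1.71e-05, estimated correlation 0.0738, but 0.0560 after quantile normalization). Distal convoluted and connecting tubule markers were higher (3.04e-05, estimated correlation 0.109). Calls near the threshold were podocyte markers (0.0337, estimated correlation 0.315, but 0.0739 without db/db replicate 05), smooth muscle and mesangium markers (0.0385, estimated correlation 0.315, but 0.0974 without that library), both higher, and lipid and cholesterol synthesis genes (0.0457, estimated correlation 0.225, but 0.119 without db/m replicate 04), lower with a median of -0.10. In that list Idi1 and Cd36 fell to log2 changes of -2.88 and -2.98. Principal cell markers (0.122) and B and plasma cell markers (0.375) were not called at 35 weeks.

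**Figure D3:**
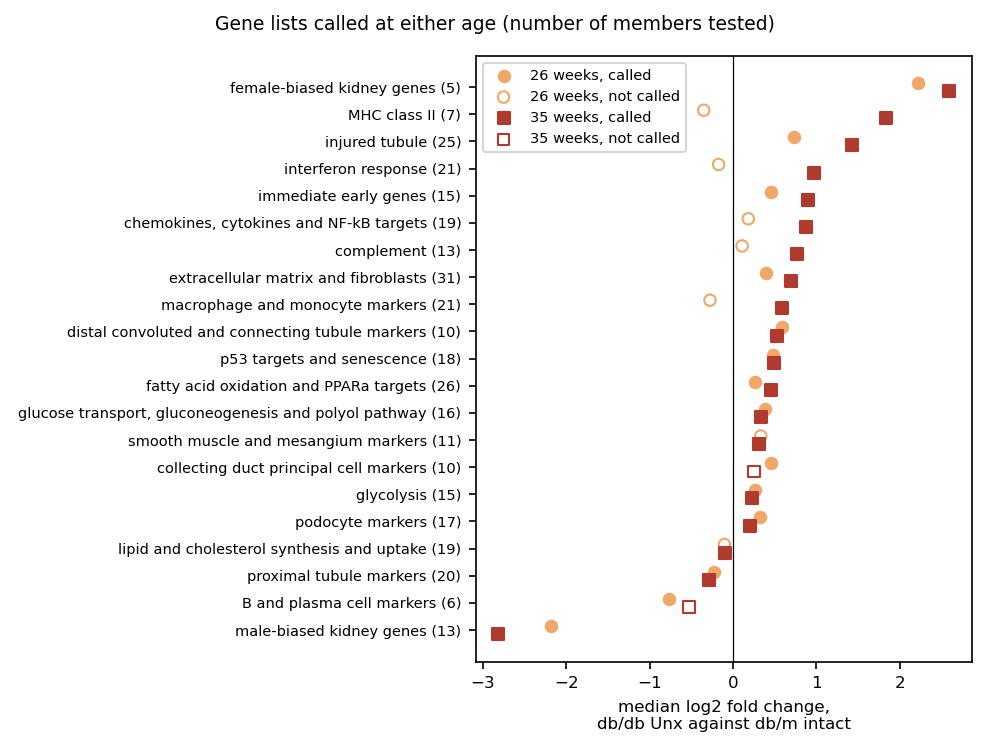
Median log2 fold change of the members of each list called at 26 or 35 weeks, db/db Unx against db/m intact. Filled symbols are lists called by camera at that age, open symbols are lists not called, and the number of members tested is in parentheses. The male-biased list lies lowest at both ages, at -2.18 and -2.81.

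The other 19 lists were called at neither age. Camera compares a list with all other genes, so an uncalled list can still differ between the groups. NRF2 scores were higher in all db/db Unx than in all db/m libraries at 26 weeks (at least -0.00698 against at most -0.0835) and 35 weeks (0.0148 against -0.0125). At 26 weeks adipocyte and urothelium scores were likewise all higher and ER stress scores all lower, and at 35 weeks renin-angiotensin scores were all lower. Oxidative phosphorylation had adjusted camera p-values of 0.906 at 26 weeks and 0.61 at 35 weeks (2.61e-07 and 3.37e-07, higher, after quantile normalization), and the mitochondrially encoded genes had 0.588 and 0.375 (called at 26 weeks after quantile normalization at 0.0358, where the median went from -0.0425 to 0.137). In the same order the values were 0.993 and 0.672 for cell cycle, 0.202 and 0.135 for NRF2 targets (0.0495 and 0.0324 after quantile normalization), 0.202 and 0.685 for ER stress, 0.354 and 0.245 for the renin-angiotensin system, 0.684 and 0.379 for the circadian clock, and 0.419 and 0.379 for heat shock. Among cell types they were 0.213 and 0.685 for thick ascending limb, 0.202 and 0.951 for intercalated cells, 0.341 and 0.619 for endothelium, 0.22 and 0.672 for T and NK cells, 0.341 and 0.375 for neutrophils, and 0.195 and 0.685 for erythroid cells. For neighbouring tissue they were 0.213 and 0.144 for adipocytes, 0.644 and 0.656 for adrenal, 0.213 and 0.623 for urothelium, 0.644 and 0.375 for lymphatic and 0.497 and 0.672 for skeletal muscle markers. Single members of uncalled lists changed. Ace went from 126 ± 26.2 to 23.9 ± 5.58 at 26 weeks (log2 -2.36 ± 0.15) and Agt from 39.6 ± 7.69 to 155 ± 23.4 (1.94 ± 0.10), and Egf changed by -0.57 ± 0.10. A list's test, median and mean had 1 sign in every called list, while in some uncalled lists, such as heat shock, they differed.

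The comparison of 35 with 26 weeks in db/db Unx asked what changes as the disease advances. It called 1526 genes, 697 higher and 829 lower at 35 weeks, of which 100 changed at least 2-fold, 89 up and 11 down. Without db/db Unx 35-week replicate 05 the count was 633, and without replicate 06 it was 759. The smallest adjusted p-values among increases were for Slc6a18 (0.49 ± 0.05, adjusted p 5.64e-07), Pnrc1 (0.71), Stat3 (0.60), Btg1 (0.69) and Cp (0.67). Among decreases they were for Smim5 (-1.05 ± 0.09, adjusted p 1.29e-09), Ell3 (-0.83), Cmbl (-0.51), Ddt (-0.40) and Selenbp1 (-0.36). Cyp27b1 went from 385 ± 116 to 144 ± 66.6, by -1.46 ± 0.24 (adjusted p 0.000511), which left it above the db/m value of 10.8 ± 3.89.

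Camera called 14 lists for age in db/db Unx, 9 higher and 5 lower. The higher ones were injured tubule (1.29e-17), the chemokine list (1.32e-15), macrophage markers (1.11e-11), interferon response (1.24e-10), immediate early genes (2.32e-10), MHC class II (2.87e-09), complement (1.92e-07), the matrix list (3.82e-06) and ER stress (0.000578). With an estimated correlation the injured tubule (0.0166), chemokine (0.021), immediate early (0.021), complement (0.0236) and ER stress (0.0485) lists held, and the other 4 did not. The rise of ER stress in db/db Unx started from scores below those of all db/m libraries of the younger age. Against db/m its median was -0.19 at the younger age, with 0 members higher and 7 lower. At the older age it was -0.01, with 5 higher and 2 lower, and the list was called at neither age. Of the 25 injured tubule genes, 14 rose and 0 fell (19 and 0 adjusted over the list alone), and of the 19 chemokine genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone). Lower lists were oxidative phosphorylation (9.12e-14), for which of 32 genes 0 rose and 19 fell (0 and 28 adjusted over the list alone), mitochondrially encoded genes (9.04e-09), male-biased genes (4.88e-08), intercalated cell markers (0.000555) and proximal tubule markers (0.0169, but 0.868 after quantile normalization). None of these 5 held with an estimated correlation, where oxidative phosphorylation had 0.172, and after quantile normalization 7 of its genes were called lower, with a median of -0.0827.

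In db/m, 999 genes were called between the ages, 368 higher and 631 lower at 35 weeks, and 13 changed at least 2-fold. Without db/m 26-week replicate 05 the count was 578. Increases with the smallest adjusted p were Ipmk (0.73 ± 0.10, adjusted p 0.000114), Cluh (0.48), Ndrg1 (0.88), Ptprk (0.44) and Khnyn (0.55), and decreases were Myl6 (-0.37 ± 0.05, adjusted p 0.0001), Ndufa4 (-0.38), Ndufa13 (-0.41), Rpl24 (-0.40) and Atp5k (-0.47). Camera called 4 lists. Oxidative phosphorylation was lower (2.28e-17), with a median of -0.19, and of 32 genes 0 rose and 20 fell (1 and 23 adjusted over the list alone). With an estimated correlation it had 0.515, and after quantile normalization 13 of its genes were called lower and 1 higher, with a median of -0.105. The mitochondrially encoded genes were lower (1.09e-05, estimated correlation 0.774, but 0.732 after the trend on exon length was removed). Podocyte markers were higher (0.0331, estimated correlation 0.774) and erythroid markers lower (0.0331, estimated correlation 0.814), and either call was lost without single db/m libraries, up to an adjusted p of 0.102 without 26-week replicate 01 for podocytes and 0.149 without 26-week replicate 05 for erythroid markers. Between db/db Unx and db/m, 338 genes were called the same way with age, 61 up and 277 down, where independent lists would share 19.0 and 38.8, and 7 were called in opposite directions.

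The interaction tested whether the disease comparison differed between the ages. It called 74 genes, 53 with a more positive change at 35 weeks and 21 with a more negative one, and the count at an unadjusted p below 0.05 was 1699. The count fell to 7 without db/db Unx 35-week replicate 05 and rose to 249 without replicate 02. The smallest adjusted p-values were for Lgals3 (0.66 ± 0.11, adjusted p 0.00711), C1qa (1.42 ± 0.26), Mgp (1.03 ± 0.18), Tnfrsf12a (0.97 ± 0.18) and Rras (0.63 ± 0.13), and for Slc4a1 (-1.68 ± 0.28, adjusted p 0.00711), Patz1 (-0.73 ± 0.13), Ell3 (-0.74 ± 0.15), Larp4b (-0.49 ± 0.10) and Susd2 (-0.45 ± 0.09). Without db/db Unx 35-week replicate 05 the adjusted p was 0.0519 for Tnfrsf12a and 0.0580 for Rras, Ell3, Larp4b and Susd2. Without db/m 26-week replicate 02 it was 0.0511 for Rras and 0.0528 for Larp4b and Susd2.

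Camera called 16 lists for the interaction. The 12 with a more positive disease effect at 35 weeks were the chemokine list (1.76e-14), macrophage markers (9.33e-14), interferon response (9.33e-14), injured tubule (2.08e-13), MHC class II (2.3e-12), immediate early genes (6.34e-07), the matrix list (1.66e-06), complement (0.000137), ER stress (0.00146), erythroid (0.0052), T and NK cell (0.0097, but 0.0577 without db/m 26-week replicate 04) and B and plasma cell markers (0.0138). The 4 with a more negative effect were male-biased genes (0.000467), thick ascending limb (0.0024), proximal tubule (0.00969) and intercalated cell markers (0.0471, but 0.293 without db/db Unx 35-week replicate 01). For ER stress the median disease effect went from -0.19 at 26 weeks to -0.01 at 35 weeks, and the list was called at neither age. Its interaction therefore reflects a lower level in db/db Unx at 26 weeks that was not seen at 35 weeks. An interaction does not show which genotype moved. Erythroid markers were called lower with age in db/m (camera 0.0331) and not called with age in db/db Unx. Thick ascending limb, T and NK cell and B and plasma cell markers were called with age in neither genotype. The chemokine and injured tubule lists held with an estimated correlation, both at an adjusted p of 0.0377, and the other 14 did not.

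**Figure D4:**
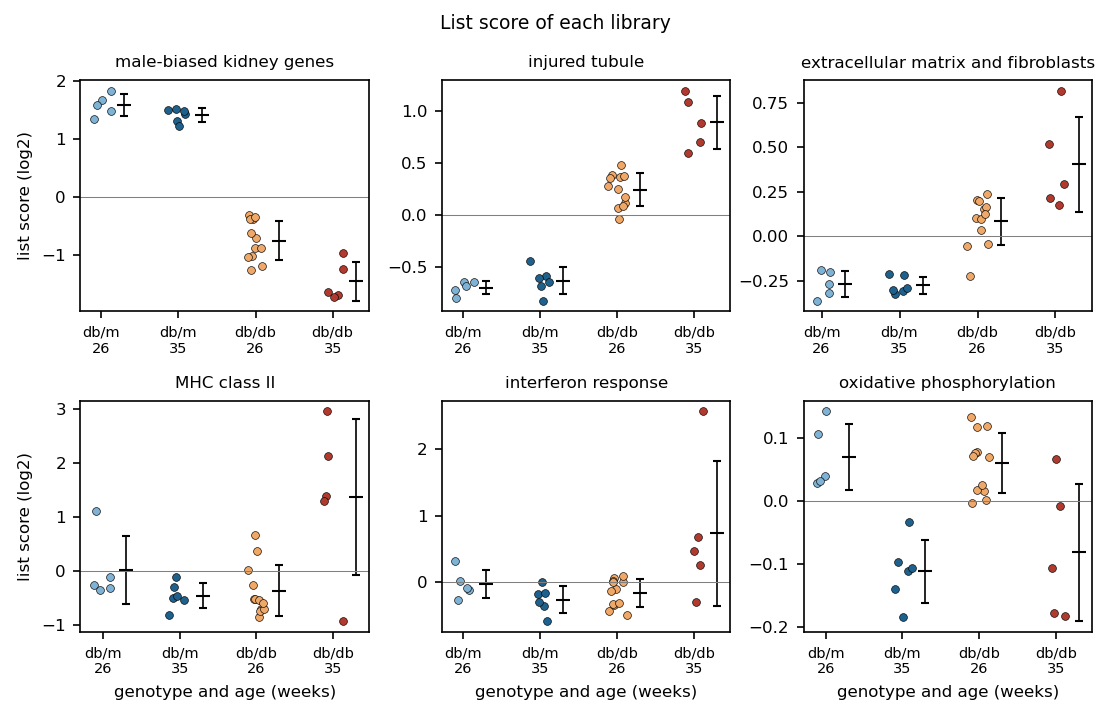
List score of each library, the mean over members of the log2 value minus the gene's mean over 28 libraries, by genotype and age in weeks. Points are libraries, and the dash and bar are the mean and SD. Male-biased scores of all db/db Unx libraries lie below those of all db/m libraries, and the MHC class II and interferon scores of 35-week db/db Unx libraries are spread widely.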

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

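The tests of single libraries, of tissue makeup, of ribosomal protein genes, of members on and off chromosome 4, and of the injured tubule and proximal tubule scores among the 26-week libraries were chosen only after the results they explain had been seen. So were the rule by which those correlations were read, the exact tests of the oxidative phosphorylation score, and the alternatives named in the methods as added.

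In groups of 5 or 6 libraries, a library is named here where its gap to the nearest other library, divided by the range of the group, passed Dixon's 95% critical value on the log2 scale. Of 372 combinations of a group with a named gene or list score, 34 passed, where chance gives about 18.6. The gap as a share of the range is in parentheses. In db/m at 26 weeks, the following libraries stood apart. Replicate 01 was highest for Susd2 (0.767) and lowest for Cyp4a14 (0.762), Cyp27b1 (0.735) and Cp (0.775). Replicate 03 was highest for Bhmt (0.849). Replicate 04 was highest for Cd74 (0.877) and MHC class II (0.830). Replicate 05 was highest for Ugt1a10 (0.800) and lowest for Slc4a1 (0.884) and smooth muscle and mesangium markers (0.765). In db/m at 35 weeks, these did. Replicate 01 was highest for S100g (0.6253) and distal convoluted and connecting tubule markers (0.671). Replicate 02 was highest for Ddt (0.739) and lowest for Bhmt (0.791), Spp1 (0.752) and Cyp4a12b (0.736). Replicate 03 was highest for Ipmk (0.686) and Cyp4a12a (0.658). Replicate 04 was highest for collecting duct principal cell markers (0.725), adipocyte markers (0.715) and urothelium markers (0.719) and lowest for Slc7a13 (0.729) and Acsm2 (0.643). Replicate 05 was highest for ER stress and integrated stress response (0.742) and lowest for Idi1 (0.742). In db/db Unx at 35 weeks, these did. Replicate 01 was highest for Cyp2j5 (0.734) and Cyp2j13 (0.713). Replicate 03 was highest for Cxcl10 (0.814) and neutrophil markers (0.711). Replicate 05 was highest for Ugt1a1 (0.883), Cluh (0.782) and Cyp4a12b (0.846) and lowest for lipid and cholesterol synthesis and uptake (0.717). Replicate 06 was highest for Cp (0.724). The 12 libraries of db/db Unx at 26 weeks were not tested in this way.

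The disease effect differed between the ages by the interaction test for 14 named genes. The difference of the log2 disease effects, 35 minus 26 weeks, is in parentheses: Lgals3 (0.66), Tgfbi (1.17), Il34 (0.95), Smim5 (-0.63), Ell3 (-0.74), Ndrg1 (-0.78), C1qa (1.42), Mgp (1.03), Tnfrsf12a (0.97), Rras (0.63), Slc4a1 (-1.68), Patz1 (-0.73), Larp4b (-0.49) and Susd2 (-0.45). Of these, 10 lost the call under at least 1 alternative. Il34 lost it without any 1 of 9 libraries, with an adjusted p up to 0.0740 without db/m 26-week replicate 04, Smim5 without any 1 of 5 libraries, up to 0.0599 without db/db Unx 35-week replicate 06, and Ndrg1 without db/m 26-week replicate 02 (0.0528). The losses of the other 7 are in the report or in the next part. The same test on lists, with the median difference of the members in parentheses, called extracellular matrix and fibroblasts (0.38), injured tubule (0.49), chemokines, cytokines and NF-kB targets (0.91), complement (0.32), interferon response (1.09), MHC class II (2.19), ER stress and integrated stress response (0.26), male-biased kidney genes (-0.46), immediate early genes (0.54), proximal tubule markers (-0.12), thick ascending limb markers (-0.28), intercalated cell markers (-0.079), macrophage and monocyte markers (0.91), T and NK cell markers (0.44), B and plasma cell markers (0.54) and erythroid markers (1.01). With an estimated correlation the chemokine and injured tubule lists held (both 0.0377) and the other 14 did not.

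For each count of called genes, 100 splits of the same libraries into groups of the same sizes were drawn, the real one included. In each of the 5 comparisons 1 split, the real one, gave as many genes. For the disease and age comparisons this argues against an arbitrary division of the libraries as their source, at that resolution. For the interaction the ages were shuffled within each genotype, which also breaks up the age differences. Its splits therefore do not test the interaction alone. The real counts and the highest of the other splits were 4713 and 2856 for disease at 26 weeks, 4357 and 3027 for disease at 35 weeks, 1526 and 1159 for age in db/db Unx, 999 and 544 for age in db/m, and 74 and 20 for the interaction.

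The first pattern was the rise of inflammatory, complement and injury lists in db/db Unx between 26 and 35 weeks. Libraries of this group differ widely, and replicate 03 lies farthest out on the second principal component. Without it, 5 of the 5 lists tested (chemokines, MHC class II, macrophage markers, complement and injured tubule) were still called higher, with a highest adjusted p of 3.57e-07, and without any 1 library of the group the highest was 3.45e-06. At a correlation estimated per list, with all libraries, MHC class II and macrophage markers were not called for age in db/db Unx (both 0.0953). This argues against a single library as the source of these 5. Replicate 02 did not take part in most of the rise, with scores of -0.92 for MHC class II, the lowest of all 28 libraries, -0.47 for macrophage markers, -0.30 for interferon response and -0.03 for complement. For the interferon response list the median log2 change fell from 0.93 to 0.38 without replicate 03, a share of 0.405, and the members called higher went from 11 to 5 of 21, although the list was still called (adjusted p 3.46e-06). It was not called with all libraries when the correlation was estimated (0.172). Most of the interferon rise may therefore come from that library. A lower share of proximal tubule would raise the markers of every other kidney cell type. The 74 podocyte, thick ascending limb, distal, principal, intercalated and endothelial markers had a median change of -0.05, against 0.79 for macrophage markers, a ratio of -0.0599, and the difference of the scores was larger at 35 weeks (0.79, exact permutation p 0.00339, two-sided, 6188 splits). Lymphoid tissue taken with the kidney would raise lymphocyte markers together with MHC class II genes. The MHC class II score rose by 1.45 more than the score of the 14 lymphocyte markers expressed (exact permutation p 0.00242), 1 of which was called higher, and Cd74 went from 374 to 1639. By camera, T and NK cell markers were not called for age in db/db Unx (0.183), but were without the filter (0.0319) and without replicate 02 (0.0435). The interaction called T and NK cell (0.0097) and B and plasma cell markers (0.0138), though not at an estimated correlation. The log2(value + 1) scale also shrinks changes of weakly expressed markers, so some lymphoid tissue is not excluded. In db/m none of these lists was called between the ages, and a batch effect of age common to both genotypes cancels in the interaction, which called all 6. With an estimated correlation the interaction kept chemokines and injured tubule, while complement (0.0766), MHC class II (0.0670), macrophage markers (0.0670) and interferon response (0.129) lost the call, so for these 4 a common batch is less well excluded. A change with age in diseased animals and a batch that affected db/db Unx alone both stay open.

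The second pattern was the lower expression of oxidative phosphorylation genes at 35 weeks in both genotypes, with medians of -0.14 in db/db Unx and -0.19 in db/m. With an estimated correlation the list was called in neither genotype (0.172 and 0.515). Quantile normalization left it called lower by camera but shrank the medians to -0.0827 and -0.105, and the members called lower from 19 to 7 and from 20 to 13. These genes are short, with a median exon length of 2124 against 4391 bases for all tested genes. After each library's trend on exon length was removed, the list was still called lower in both genotypes, with 2.73e-07 as the higher of the adjusted p-values. The trend on this length thus did not account for the whole change. The length covers all annotated exons of a gene, not the transcripts expressed, so a remaining effect of length is not excluded. Removing the trend did shrink the medians to -0.09 and -0.08, and the members called lower from 19 to 6 in db/db Unx and from 20 to 8 in db/m. The list score was still lower in db/db Unx (-0.09, exact permutation p 0.0133) and in db/m (-0.10, exact permutation p 0.00216, the smallest that 462 splits can give). Removing the trend on GC content left the medians at -0.15 and -0.20, with 1.36e-13 as the higher adjusted p. Cytosolic ribosomal protein genes, another class of short and abundant transcripts, fell too. In db/m 100% of 79 were lower at 35 weeks, 70 of them called, with a median of -0.31, and in db/db Unx 98.7% were lower, 17 of them called, with a median of -0.12. A library or RNA batch that differed between the ages could produce both, and it cannot be told apart from age, because the labels give no batch and every library of 1 age may come from 1 preparation. The change with age itself stays open as untested.

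The third pattern was the loss of male-biased kidney expression in db/db Unx males. A loss spread evenly over the proximal tubule, where these genes are expressed, would lower them no more than the tubule's own markers. The median of the male-biased list lay 1.08 below the lowest proximal tubule marker at 26 weeks, Acsm2 (difference -1.08), and further below at 35 weeks, while proximal tubule markers had medians of -0.22 and -0.29. A loss limited to some segments of the tubule was not tested and stays open. The db mutation lies on chromosome 4, and variants carried along with it could change neighbouring genes. The 7 members on other chromosomes had median changes of -2.36 at 26 weeks and -3.09 at 35 weeks, so an effect of the linked segment on its own genes does not account for them. The 6 members on chromosome 4 (Cyp4b1, Cyp2j5, Cyp4a12a, Slc7a13, Cyp2j13 and Cyp4a12b), 5 of them within 20 Mb of Lepr, had medians of -2.07 and -2.04. Among them Cyp4a12b went the other way and rose at 35 weeks. For the members that fell, a linked variant cannot be told apart from a shared cause, since every db/db animal carries the same segment. Among the 12 db/db Unx libraries of 26 weeks, male-biased scores ranged from -1.26 to -0.31, with 0.231 as the largest gap between neighbours. They were compared with 3 other scores. Pearson's r was -0.447 with the female-biased score (permutation p 0.148, adjusted 0.222, Spearman's rho -0.441 with permutation p 0.155, adjusted 0.291, and r -0.478 without the 2 farthest libraries). It was 0.242 with the injured tubule score (permutation p 0.443, adjusted 0.443, rho 0.273 with permutation p 0.392, adjusted 0.392, and r 0.00135 without the 2 farthest), so that a link with injury was neither shown nor excluded. With the proximal tubule score it was -0.498 (permutation p 0.0995, adjusted 0.222, rho -0.406 with permutation p 0.194, adjusted 0.291, and r -0.630 without the 2 farthest), opposite in sign to what a varying share of proximal tubule would give. Genotype, obesity, diabetes and surgery are confounded, hormone levels are not analysed here, and the cause stays open.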

How the results depend on the processing

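The voom weights, the removal of trends on exon length or GC content, the list tests under TMM, quantile normalization and without single libraries, and the shared calls without single libraries were chosen after the data were seen. Of the named gene changes, none reversed with median of ratios, pseudocounts of 0.1 and 10, the replicate block, a fit of only the groups compared or any library left out, those run on single genes. Those in the disease and age comparisons also kept their side of the threshold under these, and for the interaction 10 of 14 lost the call in at least 1 of them. No called list changed direction with median of ratios, TMM or quantile scaling, without the filter, with a pseudocount of 10, with the block, with either trend removed or without any 1 library, those run on lists. In at least 1 of these, 1 of the 14 lists called for disease at 26 weeks lost its call, 4 of 19 at 35 weeks, 1 of 14 for age in db/db Unx, 3 of 4 for age in db/m and 2 of 16 for the interaction, and 4, 3, 6, 4 and 4 other lists gained one.

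Counts of called genes stayed within 1.5 times the reported value except as follows and, for age in db/db Unx and the interaction, under the replicate block below. Trends were removed only for the age comparisons, and the rank-sum test and the fit of only the groups compared were not run for the interaction. Leave-outs apart, the highest counts in the order below were 4772, 4887, 2185, 1065 and 178. A threshold of 2-fold left 542, 666, 100, 13 and 28 genes in the disease comparisons at 26 and 35 weeks, the age comparisons in db/db Unx and db/m, and the interaction. With the exact rank-sum test, age in db/db Unx gave 638 genes and age in db/m gave 0, against 1980 at an unadjusted p below 0.05 and 999 with limma. For age in db/m the smallest p the rank-sum test can give is 0.433%, which the 673 non-overlapping genes reached. That number is too small for any gene to pass the adjustment over 13495 genes, so the 0 reflects the group sizes. Removing the trend on exon length left 593 genes for age in db/m. The interaction gave 41 without trend and robust step, 178 with array weights and 38 with voom weights. The cause of the other changes was not tested. Scalings moved the median change of all genes by 0.02 at most.

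Of list tests, an estimated correlation called 1 list at 26 weeks, 2 at 35 weeks, 5 for age in db/db Unx, 0 for age in db/m and 2 for the interaction. fry, which compares a list with no other genes, called 27 lists at 26 weeks, 27 at 35 weeks, 19 for age in db/db Unx, 2 for age in db/m and 10 for the interaction. Quantile normalization called 7 lists for age in db/m. It ended the call of proximal tubule markers at 26 weeks (0.485), at 35 weeks (0.0560) and for age in db/db Unx (0.868), of podocyte (0.0757), smooth muscle (0.0757) and lipid genes (0.0628) at 35 weeks and of intercalated cell markers in the interaction (0.0604), and called oxidative phosphorylation in the disease comparisons (2.61e-07 and 3.37e-07), where it is not called with the deposited scaling. The cause was not tested.

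Leaving out 1 library at a time gave 4178 to 4780 genes for disease at 26 weeks, 3751 to 4397 at 35 weeks, 633 (without db/db Unx 35-week replicate 05) to 1748 (without replicate 02) for age in db/db Unx, 578 (without db/m 26-week replicate 05) to 1140 for age in db/m, 7 to 249 for the interaction and 2740 to 3016 for the shared calls between 26 and 35 weeks. Lists called ranged over 14 to 14, 16 to 19, 14 to 17, 2 to 5 and 14 to 17. For age in db/m, 2 lists were called without 26-week replicate 01 or 02 or 35-week replicate 01. The interaction count moved by more than 1.5 times for 17 of the 28 libraries. It was 14, 30 and 37 without db/m 26-week replicates 02, 04 and 05, 48, 49, 49, 46 and 49 without db/db Unx 26-week replicates 03, 06, 07, 08 and 09, 46, 32, 37 and 46 without db/m 35-week replicates 01, 02, 03 and 04, and 122, 249, 36, 7 and 42 without db/db Unx 35-week replicates 01, 02, 03, 05 and 06. Lipid genes at 35 weeks lost their call without db/m 35-week replicate 04 (0.119), db/db Unx 35-week replicate 05 (0.0739), or db/m 26-week replicate 04, db/db Unx 26-week replicate 03 or 10 (0.0504, 0.0501 and 0.0508). Smooth muscle markers lost it without db/m 35-week replicate 02 (0.0629) and db/db Unx replicates 02 (0.0562) and 05 (0.0974). The cause was not tested.

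The replicate number was fitted as a block because groups share numbers in the labels. Same-numbered libraries did not deviate together: the mean correlation of their deviations from group means was -0.0106 over 30 pairs (range -0.135 to 0.0840, 0 above 0.1) against 0.00129 for other pairs, and 3 of 22 libraries correlated best with their own number. The numbers were therefore taken to name animals only. The replicate block gave 3919 and 4099 genes for disease, 483 and 684 for age in db/db Unx and db/m, 29 for the interaction (14 up and 15 down) and 2613 shared calls between 26 and 35 weeks. Slc4a1, Patz1, Larp4b, Smim5 and Ndrg1 lost their interaction call under it (0.0548, 0.0596, 0.0968, 0.150 and 0.0968), as did the lipid list at 35 weeks (0.0697) and intercalated cell markers in the interaction (0.0550). The cause was not tested.

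The count model planned for whole reads was not run, since the recovered counts were not whole. At 21.8 to 30.8 M (M, mega) estimated counts, 3 reads correspond to a deposited value between 0.0884 and 0.134, and a gene below that is not detectable. With 5 animals in the smallest groups, 41.8% of simulated interaction changes of 0.5 on the log2 scale were recovered, so that the 74 genes called are not a full list of what differs.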

Other observations

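Whether variants linked to the db mutation explain many calls was tested around Lepr, with the prediction written before the result was seen. Of 220 tested genes within 20 Mb of Lepr, 55 (25%) were called the same way at both ages. Other windows held as many genes and were moved gene by gene, so neighbouring windows overlap almost fully and the 8652 windows are not independent. They had a median of 22.7% and a 95th percentile of 27.3%, and 24.6% of them reached the share around Lepr. An enrichment of calls around Lepr was not seen at this window size, which does not exclude an effect on single genes such as Cyp4a14, which lies in the window.

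Fgg, Fga, Apoc3, Apob, Apoe, S100g and Kl were chosen after their values were seen, as single genes, while Calb1 and Trpv5 met the rule as distal tubule markers. Fgg had 7.45 ± 1.83 in db/m and 81.6 ± 21.9 in db/db Unx at 26 weeks, a log2 change of 3.28 ± 0.19 (adjusted p 1.94e-13), and Fga changed by 2.18 ± 0.19, Apoc3 by 1.86 ± 0.12, Apob by 1.09 ± 0.09 and Apoe by 1.19 ± 0.13. At 35 weeks the changes were 3.71, 1.94, 2.38, 1.03 and 1.91 in the same order. Log2 changes at 26 weeks were 1.20 ± 0.08 for Calb1, 1.82 ± 0.16 for Trpv5, 0.75 ± 0.10 for S100g and -0.50 ± 0.06 for Kl, and at 35 weeks 1.12, 1.35, 1.18 and -0.76. No explanation of these was tested.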
